A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

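Leaf DNA of Nipponbare seedlings aged 12 days was studied in 6 libraries, 3 IP and 3 input, per the labels, with 1 further SMRT data set that names no sample. Per the labels' protocols, IP DNA was sonicated, denatured, precipitated with an anti-6mA antibody and sequenced on a NextSeq 500. Labels gave the groups and replicate numbers, and the input libraries were not used here.

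The SMRT list holds the deposited modification score, a whole number of at least 20 on a Phred-like scale, written by the kinetics caller kinModCall per the file's columns. It also gives, per site, coverage, a context of 41 bases centred on the called adenine, the ratio of inter-pulse durations (IPD), an identification score and the methylated fraction. The median score was 23 at a coverage of 11 to 14, 28 at 25 to 49, 38 at 100 to 499 and 35 at 2000 or more. The IP peak lists hold the deposited peak score of MACS, a caller named by the peak names in the files. Peaks were called per library, and whether input served as control is not given in the sources used here. FastQC, Trimmomatic and Bowtie were named per the submitters' processing notes, with no version. Aligner settings, MACS version and genome build are not given in the sources used here.

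Coordinates of the 2 kinds of list appeared to come from different assemblies. The furthest site lay beyond the furthest peak on 3 chromosomes and before it on 9, most of all on chromosome 4 (sites to 31461851 and peaks to 35497977). Sites and peaks were therefore never laid over each other, and only densities per chromosome or per end were set side by side. A genome of either assembly was not used here. So the share of all genome adenines, gene features, gene starts, gene lists, named genes, repeat content and sites within peaks, all planned before the data were examined, were not analysed here. In place of the named genes, the text gives the regions common to all libraries ranked by their lowest percentile of score in any library (the first 5 of 10 are printed), a rule set after the data were seen.

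The planned motif background of genome adenines was replaced, after the data were seen, by adenines 12 to 17 bases from the called one in the same windows, on both strands. The fold of a motif is its share of sites over its share of these adenines. The names of 9 motifs were fixed before the data were examined, and the place of the called adenine within AGAA, CATG, ACCT and TAA was set afterwards. For bases by position, positions 14 to 20 bases away served as the outer flanks. Fractions were compared between motifs at coverage of 15 to 24 only, because the fraction of a called site fell with coverage.

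Peak overlap needed at least 1 shared bp and was computed with bedtools 2.31.1. The chance level came from 200 circular shifts along each chromosome, taking its length as the furthest peak end. Densities at the ends were compared over 12 chromosomes with an exact two-sided sign-flip permutation test, and correlations with 100000 permutations. The comparison of chromosome ends and its outer limit of 5 Mb were chosen after counts along chromosomes 1 and 4 had been seen. Blocks of high coverage joined sites covered at least 100 times that lay within 5 kb and held at least 10 of them, all set after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

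Both calculations were tested on simulated data. A motif fold of 17.0 set in 60000 simulated windows came back as 16.5, and a peak overlap of 61.1% set in 6000 simulated peaks came back as 62.3%. The first expected value written for an unplanted motif in this test had been wrong and was corrected, with the calculation itself left as it was.

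Alternatives fixed before the data were examined were a score of at least 30, coverage of at least 25, a fraction of at least 0.5, the stronger 50% of peaks, reciprocal overlap of 50% and each IP replicate left out. Others were added after the data were seen: sites covered at least 100 times left out, each context used once, flank adenines of the called strand only, equal numbers of peaks, windows of 1 kb on peak centres and an outer limit of 3 Mb.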

Results

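N6-methyladenine (6mA), a methylated form of adenine in DNA, was measured in rice. The first data set was a single genome-wide list of methylated adenines from single-molecule real-time (SMRT) sequencing, which reads a modified base from the pause of the polymerase. That list names no sample, so its tissue and plant age are not given in the sources used here. The second data set was immunoprecipitation (IP) of DNA with an antibody against 6mA, in 3 IP libraries and 3 input libraries. These libraries came from leaves of 12-day-old seedlings of the cultivar Nipponbare. Replicates 1 and 2 of the IP used an antibody from Synaptic Systems, and replicate 3 used one from Abcam. Peak lists of the 3 IP libraries were analysed, and the input libraries were not used here. The SMRT list carried no replicate, so its errors are exact Clopper-Pearson 95% intervals, which cover counting error only, or the SD over 12 chromosomes, which is not a replicate error. Nothing in the labels said whether the IP libraries came from separate plants, so the spread between them may be technical.

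The first question was how many adenines were called methylated and how they were spread over the genome. The SMRT list held 265165 sites on the 12 chromosomes, or 1 site per 1353 bp of the length spanned by the sites. Site density was 741 ± 21.3 sites per Mb (SD over 12 chromosomes). Chromosomes 1 and 3 were the sparsest, at 706 sites per Mb each, and chromosome 4 the densest, at 771 sites per Mb. The strands were near balance, with 49.9% of sites on the plus strand (95% interval 49.67 to 50.05%), and the interval left out 50% on 1 of 12 chromosomes.

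The methylated fraction of a site, the caller's estimate of the share of molecules modified there, had a median of 0.78 with quartiles of 0.621 and 0.953. A fraction was given for 255998 sites, and it was missing for the 9167 sites covered 10 times or less. Fractions of at least 0.9 were held by 31.8% of these sites, and fractions under 0.5 by 11.5%. The median fraction fell with coverage, from 0.926 at 11 to 14 reads to 0.634 at 25 to 49 reads. These shares therefore depend on depth. Coverage had a median of 18 reads, with 5th and 95th percentiles of 11 and 31. The modification score had a median of 25, and 73.6% of sites scored under 30. With a score of at least 30 the list fell to 69876 sites, and with coverage of at least 25 to 39217, so the number of sites followed the threshold.

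The second question was in which sequence the called adenines lay. Called adenines were concentrated in GAGG, with the adenine at the second base. GAGG held 18.9% of sites (95% interval 18.8 to 19.1%) against 1.86% of adenines in the flanks of the same windows, a fold of 10.1 ± 0.33 (SD over 12 chromosomes). It ranked first of the 64 words of 4 bases with the called adenine at the second base. AGG as a whole held 33.5% of sites, at 6.24 ± 0.185 fold, and GAG held 28.0%, at 4.61 ± 0.0918 fold.

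**Figure D1:**
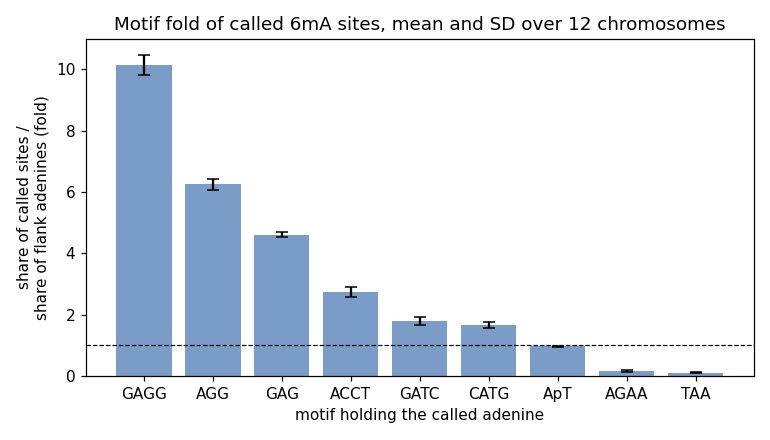
Fold of 9 motifs (x axis) among called sites over flank adenines (y axis, ratio of shares); bars are means and error bars SD over 12 chromosomes, and the dashed line marks a fold of 1. GAGG stands at 10.1, AGG at 6.24 and GAG at 4.61, while AGAA and TAA lie below 1.

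Among the other motifs fixed in advance, ACCT was 2.75 ± 0.165 fold, GATC 1.79 ± 0.119 fold and CATG 1.67 ± 0.0991 fold. GATC is the target of the Dam methyltransferase of bacteria. Over all sites, GATG stood at 2.15 fold and GATA at 1.37, against 1.78 for GATC. CATA stood at 3.29 and CATC at 2.15, against 1.68 for CATG. With T as the last base, GATT was 0.317 fold and CATT 0.398. ACC as a whole was 2.78 fold, against 2.76 for ACCT. None of these excesses was thus particular to the fixed motif. In AGAA and TAA a single place of the called adenine was examined. AGAA, with it at the first base, was depleted at 0.156 ± 0.0237 fold, and TAA, with it at the second base, at 0.109 ± 0.00847 fold. Both stayed below 1 but moved with the choice of sites, AGAA to 0.328 and TAA to 0.172 with coverage of at least 25, and AGAA to 0.0815 with a fraction of at least 0.5. ApT, a site of 6mA in green algae, held 26.9% of sites against 27.8% of flank adenines, a fold of 0.967 (interval 0.961 to 0.973). That call was lost with sites of a fraction of at least 0.5 (0.994) and turned to 1.02 with flank adenines of the called strand only. Among the 64 words of 4 bases with the called adenine at the second base, GACC followed GAGG at 4.71 fold. AAGG came next at 4.66, then TAGG at 4.16 and CAGG at 3.53. The lowest was TACA at 0.0286 fold. Sites with ACC made up 14.1% of the list.

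Sites at GAGG were methylated to a slightly higher fraction than other sites when depth was held between 15 and 24 reads. The mean fraction was 0.796 ± 0.00491 at GAGG and 0.757 ± 0.00158 elsewhere (SD, n = 12 chromosomes). GAGG was higher on 12 of 12 chromosomes, by 0.0393 ± 0.00464 (p = 0.000488, the smallest the exact two-sided sign-flip permutation test can give). The chromosomes belong to a single list and are not replicates, so this p-value describes that list only. In the same range of coverage, the mean fraction was 0.822 at ACC sites, 0.794 at ApT sites, 0.758 at AGG sites as a whole, 0.720 at sites with a second adenine after the called one and 0.688 at AG followed by another base than G.

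Bases beyond the motif were also shared. The position 4 bases after the called adenine held A in 66.1% of sites, against 27.6% in the outer flanks. Position 6 held C in 64.3% against 22.6%, and position 7 held A in 58.5% against 27.6%. Position 3 held A in only 1.58% of sites. The excess of A at position 4 was present in each of 5 classes of following bases, from 55.4% of AGG sites to 79.7% of ApT sites. The classes were AGG, AG followed by another base than G, ACC, ApT and AA. Sites with AC followed by another base than C were not examined. Within AGG, the GAGG sites held A there in 50.8% of cases.

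**Figure D2:**
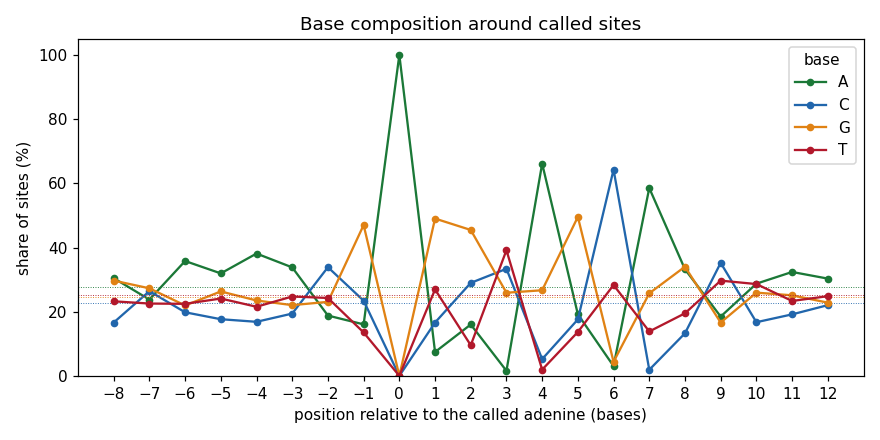
Share of sites (y axis, %) with each base at positions before and after the called adenine (x axis, bases, 0 is the called adenine); dotted lines give the share in the outer flanks of the same windows. A at position 4 reaches 66.1% and C at position 6 reaches 64.3%.

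The third question was how the IP peaks were spread and how far the libraries shared them. The IP libraries gave 20420 ± 4349 peaks on the 12 chromosomes (SD, n = 3), covering 49.3 ± 6.58 Mb or 13.2 ± 1.76% of the length spanned. Replicate 1 had 18298 peaks with a median width of 2140 bp, replicate 2 had 17539 of 2364 bp, and replicate 3, with the other antibody, had 25422 of 2006 bp. Covered length was 44.2 Mb, 47.0 Mb and 56.8 Mb in that order. Read depth of these libraries is not given in the sources used here, so the precision of the peak numbers is unknown.

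Replicates 1 and 2 shared far more of their covered bases than either shared with replicate 3. The Jaccard value, the length covered in both lists over the length covered in either, was 0.534 for replicates 1 and 2, 0.339 for replicates 1 and 3 and 0.337 for replicates 2 and 3. The means of 200 circular shifts were 0.0659, 0.0721 and 0.0746, and the highest shift of any pair was 0.0781. A peak of replicate 1 overlapped one of replicate 2 in 74.3% of cases (interval 73.6 to 74.9%; 23.2% under shifts) and one of replicate 3 in 67.2% (66.5 to 67.9%; 30.0% under shifts). Of the peaks of replicate 3, 49.3% overlapped replicate 1 and 48.8% replicate 2. With 1 library of the second antibody no test between antibodies was possible.

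**Figure D3:**
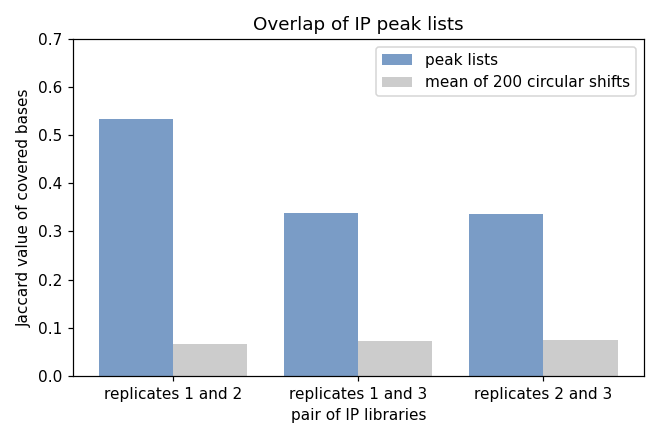
Jaccard value of covered bases (y axis) for each pair of IP libraries (x axis); blue bars are the peak lists and grey bars the mean of 200 circular shifts. Replicates 1 and 2 reach 0.534, and the pairs with replicate 3 reach 0.339 and 0.337.

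Peaks with a higher score, as given by the authors within each list, were shared more often. In the lowest quintile of replicate 1 by score, 43.9% of peaks overlapped replicate 2, and in the highest quintile 98.6% did. Against replicate 3 the same quintiles gave 51.4% and 84.3%. Of the replicate 1 peaks, 9913 (54.2%, interval 53.5 to 54.9%) overlapped a peak in both other libraries. After merging overlapping peaks of all libraries, 9783 of 32582 regions held a peak of each library, and 10583 regions were held by replicate 3 alone.

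The regions common to all libraries with the highest rank of score in their weakest library lay on several chromosomes. First was chromosome 2 from 10343407 to 10347884, with the score of 3100 that was the highest in each list. Replicate 2 held 5 peaks with that score and replicate 3 held 2, and whether 3100 is an upper limit of the scale is not given in the sources used here. Next were chromosome 7 from 6266476 to 6269364 and chromosome 5 from 18830801 to 18833286, with scores of 2104 and 1922 in replicate 1. Chromosome 6 from 19968223 to 19972070 and chromosome 10 from 18605255 to 18614751 followed, with 1789 and 2553 in replicate 1. The build behind these coordinates is not given in the sources used here, and genes at these positions were not analysed here.

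IP peaks were sparser near chromosome ends, and SMRT sites were not detectably so. In the outer 5 Mb at each end, replicate 1 had 41.6 ± 5.86 peaks per Mb against 53.7 ± 5.90 in the interior (SD, n = 12 chromosomes). Replicate 2 had 40.8 ± 5.49 against 51.0 ± 5.27, and replicate 3 had 62.6 ± 4.32 against 71.8 ± 5.84. The mean log2 ratio of ends over interior was -0.37, -0.33 and -0.20, lower at the ends on 12 of 12 chromosomes in each library (p = 0.000488, the smallest the exact two-sided sign-flip permutation test can give; Benjamini-Hochberg adjusted p = 0.000651 over 4 lists). Over the libraries the mean log2 ratio was -0.30 ± 0.09 (SD, n = 3). For the sites the log2 ratio was -0.01 ± 0.08 (SD, n = 12 chromosomes; p = 0.595 by the same exact permutation test). Whether sites and peaks differ in this ratio was not tested. Single ends were not tested either, and they need not be sparse. In each library, each of the first 5 windows of 1 Mb on chromosome 4 was denser than the interior of that chromosome. In replicate 1 these windows held 57 to 90 peaks, against 51.9 per Mb in the interior. Chromosomes are not replicates, and these p-values describe these lists.

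**Figure D4:**
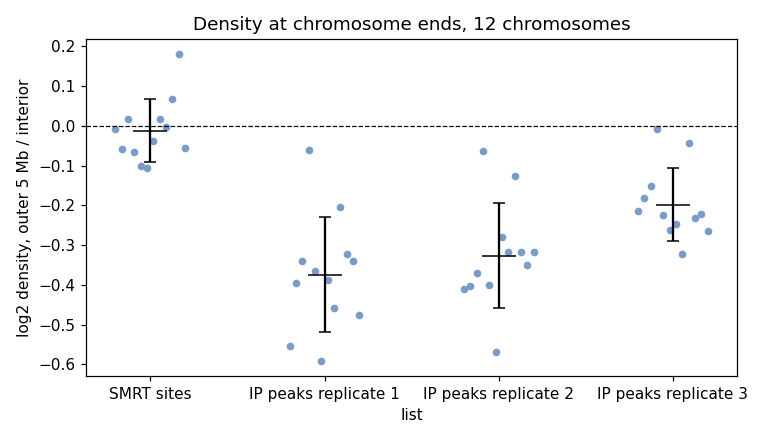
Log2 ratio of density in the outer 5 Mb of both ends together over the interior (y axis) for the SMRT sites and each IP peak list (x axis); points are the 12 chromosomes, black bars the mean and SD, and the dashed line marks equal density. The IP means lie at -0.37, -0.33 and -0.20, and the site mean at -0.01.

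In windows of 1 Mb, peak numbers varied by 27.7%, 25.01% and 19.8% (coefficient of variation) in replicates 1, 2 and 3, against 14.3%, 14.6% and 12.1% for random counts of the same mean. The densest window of replicates 1 and 3 was chromosome 5 from 10 to 11 Mb, with 91 peaks in replicate 1, and that of replicate 2 was chromosome 10 from 5 to 6 Mb, with 79. The sparsest window of replicates 1 and 2 was chromosome 2 from 32 to 33 Mb, with 20 and 22 peaks, and that of replicate 3 was chromosome 1 from 1 to 2 Mb, with 37.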

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

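The sites and peaks on unplaced sequences entered no comparison above, and their numbers are given because they exceed the 3 that a count of 0 allows. The tests of the classes of following bases, of dilution, of the IPD ratio of the single block, of the GC content of blocks and of peak width by shared bases were chosen only after the result was seen.

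The unplaced sequence of the SMRT list held 125 sites, at 728 per Mb with a median fraction of 0.824, close to the density of the chromosomes. Unplaced sequences held 39 peaks in replicate 1, 21 in replicate 2 and 53 in replicate 3. No biological explanation was tested for these values.

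Bases 3 to 7 positions after the called adenine were shared by sites of otherwise different motifs. Weakly identified calls are argued against, because A at position 4 was no more frequent at identification scores of 3 to 9 (65.4%) than at 20 or more (66.3%), a difference of -0.887 percentage points. Base composition of the windows is argued against too, as the excess was at least 2.12-fold in each tercile of windows by GC content. A sequence effect of the kinetics call on the polymerase may account for the pattern, since A at position 4 was at least 55.4% in each of the 5 classes examined. A methyltransferase that reads the same bases was not tested, and stays open.

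In 55 blocks, which were chosen for coverage and number of sites, sites lay 11.7 times as densely as elsewhere (8.53 against 0.727 per kb), with a median coverage of 523 against 18 and a median fraction of 0.23 against 0.785. The block with the most sites was chromosome 8 from 26160811 to 26189476, with 360 sites. Depth that lets small kinetic changes pass is argued against for the block on chromosome 10 from 23553241 to 23587274, whose median IPD ratio was 4.125 against a median of 2.97 elsewhere. It could account for 53 of the 55 blocks, with a median below the lower quartile of 2.43 elsewhere and of 1.55 over the sites of all blocks. The median IPD ratio of called sites already fell from 3.39 at 11 to 14 reads to 2.12 at 50 to 99. Choosing blocks by coverage thus lowers the ratio by itself, so for these 53 blocks it cannot decide. Dilution of normally modified sites by extra reads would add no sites and would keep their motifs. The sparsest block held 3.73 sites per kb. A block ran from its first to its last site, which raises the density of short ones, but the longest, of 37788 bp, held 8.97 per kb. Density thus argues against dilution alone for the blocks as a set, whose choice asked only for 10 sites joined within 5 kb. GAGG held 8.15% of block sites against 19.1% elsewhere. GAGG among the flank adenines of the blocks was not counted, so that share cannot decide. Coverage times fraction was 7.17 times that of other sites, but the choice of blocks by coverage raises it by itself, so it cannot decide. DNA of another base composition stays open, since mean GC of the outer flanks was 42.9% against 47.2%, or -6.14 SD of random runs of sites. No biological explanation was tested.

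Replicate 3 peaks overlapped replicates 1 and 2 less than these overlapped each other. More peaks in replicate 3 are argued against, as the Jaccard gap between the pairs 1 and 2 and 1 and 3 was 0.202 with 17539 peaks from each library. Peak width was open by the share of overlapping peaks in windows of 1 kb, where the gap was 9.001 points against 7.07 as first measured, under a bound for exclusion of 10 that the first gap did not reach either. By shared bases the gap was 0.188 in these windows against 0.195, which argues against width. Another antibody and another library cannot be told apart, because 1 library used the second antibody.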

How the results depend on the processing

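The alternatives on coverage of at least 100, contexts used once, called-strand flanks, equal peak numbers, windows of 1 kb and the outer 3 Mb, and those of the end and density comparisons, were chosen after seeing the data. The GAGG fold ranged from 8.20 to 12.0 over 6 alternatives, all above 1. The site number of 265165 fell to 69876 at a score of at least 30 and to 39217 at coverage of at least 25, by fewer sites entering. With the stronger 50% of peaks, the mean number per library was 10210, again by construction. The replicate 1 peaks found in both other libraries were then 4162, with fewer peaks entering in each list. The share of replicate 1 peaks found in another library fell too, from 74.3% to 70.8% for replicate 2 and from 67.2% to 57.9% for replicate 3. Without 1 replicate, the peaks per library ranged from 17918.5 to 21860, the shared peaks, then between a single pair of libraries and so a looser count than the 9913 in all, from 11997 to 13588, and the log2 ratio of peak density at the ends from -0.35 to -0.26. The ends of the SMRT sites changed sign to 0.0028 with the outer 3 Mb (exact permutation p = 0.952). The ApT fold turned to 1.02 with flanks of the called strand only, and the cause was not tested. No paired analysis was possible because the input libraries that share replicate numbers with the IP libraries have no values used here. Alternatives on gene features, gene starts, gene lists, repeats, sequence of peaks and sites in peaks were not run. Depth limits the fraction, which was missing at coverage of 10 or less, and the depth of the IP libraries is unknown.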

Other observations

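The tests of peptides, ApT pairs and density over chromosomes were chosen after the result was seen.

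Many sites lay in sequence that occurs several times in the list. Of 229878 distinct contexts of 41 bases, 11029 occurred at least 2 times and held 46316 sites, or 17.5% of the list. The most frequent occurred 157 times. Median fraction was 0.811 in repeated contexts and 0.773 in single ones, and GAGG held 21.7% and 18.3% of them. One context, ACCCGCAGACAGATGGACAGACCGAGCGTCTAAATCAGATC, was called 131 times on 12 chromosomes, with a mean fraction of 0.917 ± 0.105 (SD over the copies with a fraction). Its translation PQTDGQTERLNQI holds a peptide typical of the integrase of Ty3 retrotransposons, mobile elements that copy themselves through RNA. A second, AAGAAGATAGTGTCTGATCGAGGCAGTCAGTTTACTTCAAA, was called 110 times with a fraction of 0.727 ± 0.143 (SD over 104 copies) and translates to KKIVSDRGSQFTS.

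Either of 2 integrase peptides was encoded by 41 repeated contexts with 449 sites, by 75 of 218849 single contexts (0.0343%) and by 0 of the repeated contexts read backwards. The peptides were picked from the most repeated contexts, so these counts do not test the origin of the repeated sites.

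Symmetric methylation of ApT would place calls on both strands. At the deposited threshold 0.328% of ApT sites were so paired, in 117 pairs, against 73.5 ± 12.1 pairs at distances of 31 to 40 bp (SD over 20 distances). How often the second strand of a symmetric site would pass the call was not measured, so symmetric methylation stays open. GATC sites were paired in 1.504% of cases and CATG sites in 0.0263%.

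Pairs of sites 4 bp apart on the same strand numbered 1497, against 309 ± 77.5 at distances of 31 to 40 bp (SD over 10 distances). Position 4 held A in 66.1% of sites against 27.6% in the outer flanks. More adenines could thus be called at that distance, which the count does not allow for. That share of A was 2.39 times that of the outer flanks, while the pairs stood at 4.84 times the mean at 31 to 40 bp. The number of adenines alone therefore falls short of the excess, and which of them could be called was not examined. On opposite strands, pairs with the minus-strand site 5 bp to the right of the plus-strand site, in the direction of rising coordinates, numbered 433, and pairs with it 5 bp to the left numbered 108. The mean per signed distance of 31 to 40 bp on either side was 73.5 ± 12.1 (SD over 20 distances).

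Median fraction and GAGG share fell with coverage. The fraction was 0.926 at 11 to 14 reads, 0.721 at 20 to 24, 0.451 at 50 to 99 and 0.158 at 2000 or more. GAGG held 20.8%, 18.1%, 13.9% and 4.19% of sites in the same ranges. The last range held 787 sites. These are shares of sites, and the GAGG fold over flank adenines did not fall likewise. It was 10.5 at coverage of at least 25, against 10.1 for all sites, and was not computed within each range. Sites in the blocks of high coverage had a mean outer-flank GC of 42.9% against 47.2% elsewhere. Depth and sequence therefore cannot be told apart at the highest coverage. With each context used once, A at position 4 was held by 67.2% of contexts.

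Chromosomes with more SMRT sites per Mb also had more IP peaks per Mb, in 3 correlations over 12 chromosomes. Pearson's r was 0.802, 0.776 and 0.824 for replicates 1, 2 and 3 (permutation p = 0.00222, 0.00336 and 0.00127, Benjamini-Hochberg adjusted p = 0.00333, 0.00336 and 0.00333). Spearman's rho was 0.713, 0.545 and 0.594 (permutation p = 0.0118, 0.0706 and 0.0460, adjusted p = 0.0353, 0.0706 and 0.0690). Without chromosomes 1 and 3, the farthest from the median site density, r was 0.463, 0.403 and 0.516 (permutation p = 0.181, 0.246 and 0.126). Pearson's r thus passed the test only with those chromosomes, and it stayed above 0 without them, over a narrower range of site density. Common variation of both marks is a candidate explanation that the lowest r of 0.776 cannot settle. Mean r was 0.713 without sites covered at least 100 times and 0.674 at a score of at least 30.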
